A study of Mus musculus with 5 samples.

How the data were processed

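The series holds 5 one-colour microarrays of total RNA from mouse tumour cell lines. The lines were grown out of soft tissue sarcomas of mice in which doxycycline switches on a fusion of EWS and ATF1, the protein that drives clear cell sarcoma. Per the labels, cells were harvested 3 h or 48 h after exposure to doxycycline. There is 1 array for each of 5 groups, namely the 3 h control, 3 h low dose, 3 h high dose, 48 h control and 48 h high dose. The doxycycline concentrations, and whether the control cultures received any, are not given in the sources used here. Nor is the tumour line behind each array, so differences between arrays can include differences between lines. RNA was extracted on columns and labelled with Cy3, per the labels' protocols.

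Per the file headers, each array was scanned as 1 colour and read with Agilent's extraction software, which the submitters' processing notes name as Agilent Feature Extraction 10.7.3.1. The deposited values are spot intensities on a linear scale. The processed intensity was background-subtracted and spatially detrended within each array by that software, per the file headers, and it was not normalised between arrays. The deposited value table matched the linear processed signal of its own array within 0.001 on the log2 scale for 99.4% of probes, so it is linear and neither centred nor scaled between arrays. Its column medians were 38.6, 32.7, 32.2, 38.1 and 24.1 in the order of groups above. All 5 arrays lay on 1 slide and were read in 1 scan, so slide and scan do not separate the groups.

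Each array had 59305 spots outside the controls, for 55681 probes. Spots that the software marked as outliers, between 111 and 146 per array, were left out. No spot was saturated. Signals were taken to log2, the 75th percentile of each array was subtracted, and the spots of a probe were averaged. A probe counted as above background where at least 0.5 of its spots were marked well above background. This held for 55.6%, 60.0%, 59.7%, 59.9% and 55.5% of probes in the same order of groups. The files carry accessions and no gene symbols. Accessions were matched without versions to the RefSeq gene table of assembly GRCm38.p6, used for names only, because the file headers name an older build. Of 27016 probes with a curated RefSeq accession, 26403 matched, and 26413 of all probes received 1 symbol, 0 received several and 29268 received none. The 20016 named genes include 5337 with more than 1 probe, and the probe with the highest mean level over the 5 arrays stood for its gene.

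With 1 array per group there are no replicates, and no p-value is given for any difference between 2 arrays. A gene was called higher or lower at a 2-fold difference, a log2 difference of 1 or more in size, if it was above background on both arrays. Where all probes of a gene were below background on 1 array, only a bound was given. It compares the brighter array with the dim array's lowest signal above background, or with the probe's own signal if that was higher. Technical error came from 2 sources. Probes spotted 10 times gave a median SD between spots of 0.0887 to 0.0918 for a log2 difference, depending on the comparison. The software's error model gave about 0.204 for most genes with 1 spot. Neither holds the variation between cultures or labellings. In simulated data with spot noise at SD 0.286 and 200 changed genes among 14005, the 2-fold rule in the 3 h high-dose comparison recovered 97.0% of genes changed by 1.50 on the log2 scale and 100% at 2.00 and 3.00, with 5 false calls.

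The 23 gene lists were fixed before the data were examined, as were the rule for named genes and most alternatives. For each list the median difference of its measured members was set beside 10000 random lists of equal size, drawn from the same 20 bins of mean expression, and called outside when it left their central 95%. The listed names Icer, Mx1, Mx2, Col6a3 and Cd68 found no gene on the array. Among 200 simulated lists with no change, 7.00% fell outside. Their noise was independent between genes, so this is not the rate for lists whose genes vary together between cultures. Between the control arrays 6 of 22 scored lists fell outside, against 9 of 23 for the high and 10 of 23 for the low dose at 3 h. The only test was a limma fit (version 3.58.1, in R 4.3.3) of the 4 control and high-dose arrays with terms for time and high dose. It leaves 1 residual degree of freedom, uses the intensity trend in eBayes and adjusts by Benjamini-Hochberg at 0.05, over genes above background on at least 2 of the 4 arrays. On simulated data of 14601 genes, that fit recovered 71.6%, 86.6% and 93.9% of genes changed 4-fold, 8-fold and 16-fold, with 12 false calls. The simulated noise had the spread already moderated by eBayes, and the changes were equal at both times. These rates can therefore exceed those on the real arrays. In the fit an effect at 1 time only counts as error, so few calls do not show that genes were unchanged. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

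Named genes are those with an ordinary symbol. For both high-dose comparisons with the control of the same time, the rule took the 10 largest rises and 10 largest falls, the 3 largest bounds in each direction and up to 4 members of each list at 2-fold. For the other 3 comparisons it took the 5 largest rises and falls, and for the limma fit the 5 lowest p-values per direction past the threshold. Fos, Ewsr1 and Atf1 were always taken. Not all of these are printed, some genes that the rule takes are not reported here, and a few list members outside the rule are given as examples chosen after their values were seen. Alternatives covered scaling, background correction, the deposited value table, the filter on dim probes, the choice of probe, outlier spots, the scanner error and the random lists. The normexp alternative (offset 50) used the median spot signal, because the files carry no mean spot signal. The use of the other time's control array, or of both, was added after seeing the data.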

Results

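Gene expression was measured on 5 arrays, 1 per group, in mouse sarcoma cells whose EWS/ATF1 fusion gene is switched on by doxycycline. A control and a high dose were sampled at 3 h and at 48 h, and a low dose at 3 h only. The comparisons ask which genes follow the induction of the fusion early and late, and at which dose. Between 30892 and 33428 of 55681 probes were above background on each array. The 75th percentile of signal was 725, 588 and 556 for the 3 h control, low-dose and high-dose arrays, and 649 and 420 for the 48 h control and high-dose arrays. No difference below has a replicate check. Which tumour line gave each array is not given in the sources used here, so a difference between arrays can include one between lines. The spread between replicate spots (median SD near 0.09) and the scanner error (about 0.20) cover technical error within an array only, and all levels are log2 values relative to the array's 75th percentile.

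Fos, which encodes a subunit of the AP-1 transcription factor and which the study's title names, was higher after doxycycline at both times and both doses. Its level was -2.22 on the 3 h control array, -0.50 at the low dose and 2.18 at the high dose, a 21.1-fold difference between high dose and control (log2 difference 4.40, scanner error 0.0660). At 48 h it was -2.22 in the control and 2.86 at the high dose, a 33.7-fold difference (5.07, scanner error 0.0654). The control arrays differed by 0.01. The probes for the 2 genes joined in the fusion stayed under 2-fold. Ewsr1 differed by 0.12 at 3 h and 0.48 at 48 h between high dose and control, and Atf1 by 0.15 and -0.33, with 0.23 and 0.21 on its second probe. The probe sequences were not analysed here, so whether these probes detect the fusion transcript is unknown, and they do not check its induction.

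**Figure D1:**
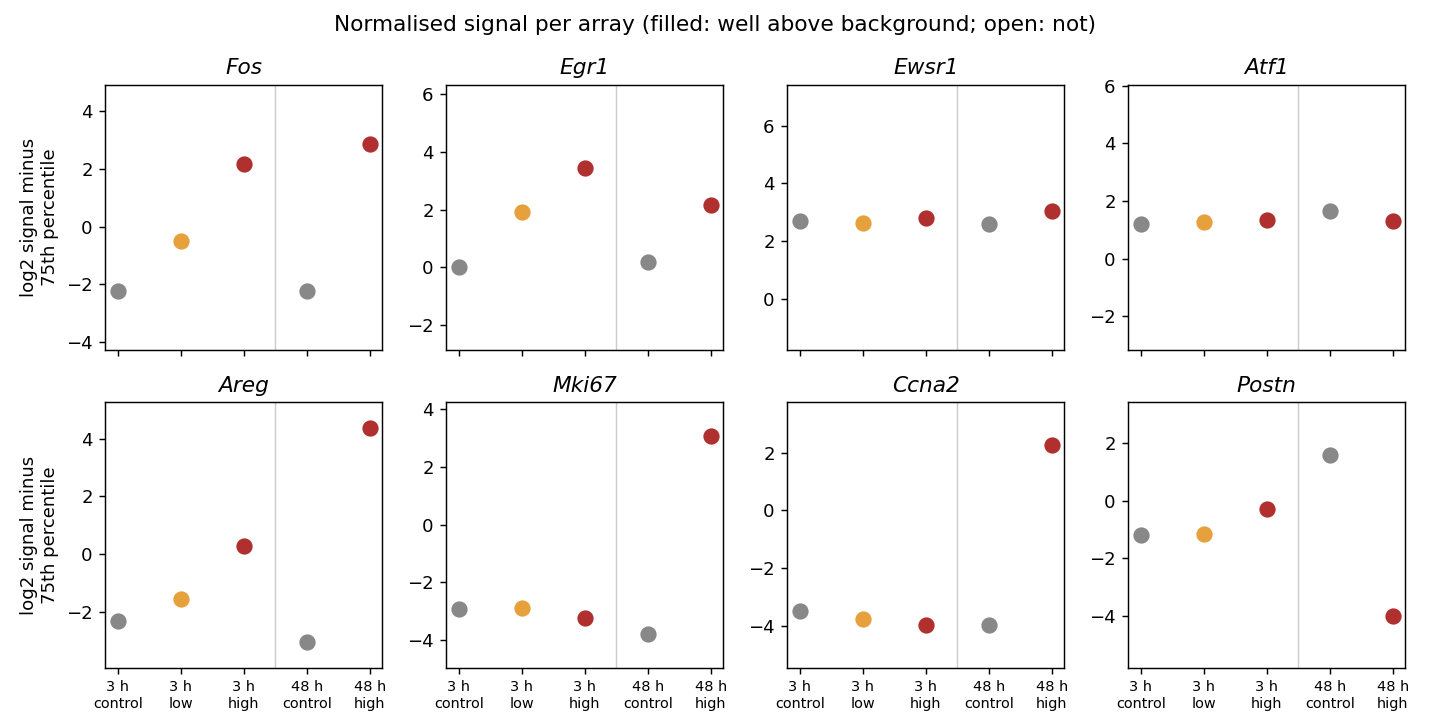
Normalised signal of 8 genes on the 5 arrays, on the y axis as log2 signal minus the array's 75th percentile, with 1 point per array and no replicates. Fos rose from -2.22 on the 3 h control array to 2.18 at the high dose, while Mki67 and Ccna2 were high on the 48 h high-dose array only among the 5 arrays.

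After 3 h of the high dose, immediate early genes and genes of growth factor signalling were higher than in the 3 h control. Of 30 measured members of the immediate early and AP-1 list, 11 were at least 2-fold higher and 0 lower, with a list median of 0.70 that lay above all 10000 random lists. Beside Fos these included Egr1, an early zinc finger transcription factor, at 3.42, the phosphatase gene Dusp2 at 2.49 and Ccn1, which encodes a secreted matrix-associated protein, at 2.35. In the list of ERK pathway output, 10 of 23 members were higher and 1 was lower (median 0.62, percentile 100). The EGF receptor ligand genes Areg and Ereg were higher by 2.59 and 2.58. The lower member was the cyclin gene Ccnd1 at -2.43, and its difference from the 48 h control was -0.27. Of 28 CREB and cAMP targets, 6 were higher and 0 lower (median 0.45, percentile 100), among them Npas4 at 2.52 and Dusp1 at 1.61. These lists share members, such as Fos, Egr1 and Areg, so their medians are not independent.

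Targets of TGF-beta and BMP signalling were also higher at 3 h, with 5 of 19 members at 2-fold and 0 lower (median 0.33, percentile 100). Pmepa1 stood at 3.40 and Ccn2, encoding a secreted matrix-associated protein, at 1.84. Against the 48 h control array the same values were 1.01 and 1.45, while the list median was 0.49. In other lists, the receptor kinase genes Kit and Ret were higher by 1.37 and 1.58, and the growth arrest gene Gadd45a by 1.66, which fell just short of 2-fold against the 48 h control.

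Interferon-induced genes and genes of cholesterol synthesis were lower at 3 h of the high dose. In the interferon list 5 of 18 members were at least 2-fold lower and 0 higher, and the median of -0.78 lay below all random lists. Ifit3 was at -1.62, the GTPase genes Igtp and Irgm1 at -1.46 and -1.37, and Ifit1 at -1.26. Against the 48 h control the median was -0.61, with Irgm1 at -0.25 and Igtp at -0.91. The cholesterol list had a median of -0.48 (percentile 0), with 1 of 20 members lower at 2-fold, and against the 48 h control the median was -0.32. The respiratory chain list had a small shift of -0.13 (percentile 0.100), with 0 of 24 members at 2-fold, and it turned to 0.04 against the 48 h control. Cytokines and NF-kB targets moved both ways, with 2 of 14 higher and 3 lower around a median of 0.23 (percentile 98.2), which was -0.23 without the filter on dim probes and 0.05 (percentile 68.3) against the 48 h control. Lif was at 1.72 and Tnfaip3, an inhibitor of NF-kB, at 1.41, while the chemokine genes Cxcl5 and Ccl7 were at -2.80 and -2.15. Of these, Lif, Tnfaip3 and Ccl7 did not pass 2-fold against the 48 h control, at 0.94, 0.99 and -0.64. Adipocyte genes had a median of -0.58 over 4 members (percentile 0.620), none of them at 2-fold, -0.33 (percentile 3.18) without the filter and -1.29 (percentile 0) against the 48 h control. The cell cycle list did not move at this time, with 0 of 26 members at 2-fold and a median of -0.04 (percentile 34.8). Medians inside the random interval were also found for the melanocyte (0.17), neural crest (0.17), Schwann cell (-0.01), neuronal (-0.04), p53 (-0.09), ATF4 (0.00), hypoxia (0.03), matrix (-0.10), immune cell (0.09), endothelial (0.28), epithelial (0.04), skeletal muscle (0.01) and reference gene (0.06) lists. With bounds included the medians were 0.21 for the Schwann cell, -0.26 for the immune cell, -0.07 for the muscle, 0.36 for the epithelial and 0.30 for the melanocyte list. Against the 48 h control, the neural crest list (0.20, percentile 98.3) lay above the interval, and the hypoxia (-0.18, percentile 0.550) and immune cell (-0.37, percentile 1.42) lists lay below it.

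In all, 261 genes were higher and 202 lower at 2-fold among 14005 measured on both arrays, or 3.31%, and a further 106 and 84 passed 2-fold as bounds. The control arrays of 3 h and 48 h differed from each other in 542 of 14018 genes, or 3.87%. The number of calls alone thus does not set the high dose apart from a difference between controls. Other large rises at the high dose were Ifna5 at 4.16, Zfhx2 at 4.08, Krtap4-16 at 3.64, Wdr92 at 3.60 and C2cd4b at 3.17. The levels of Ifna5, Zfhx2 and Krtap4-16 on the low-dose array were -3.87, -4.14 and -4.09, near the dim end. Ivd, an enzyme of leucine breakdown, was at least 145-fold higher and Cts8 at least 23.5-fold lower than on the 3 h control array. Ivd was at a level of -7.07 there and of 2.23 on the 48 h control array, above its level at the high dose, and Cts8 was below background on the 48 h control array as at the high dose. Several other large values held against the 3 h control array and not against the 48 h control. Nrxn3, Mpp4 and Dpf1 were at -4.81, -3.31 and -3.05 against the former but at -0.19, -0.02 and -0.38 against the latter, and Pold3 was at 4.01 and 0.01. A second Dpf1 probe was higher by only 0.38 on the 3 h control array than the mean of the other arrays. Ctss, a protease of antigen-presenting cells, was at -4.01 and Cd5l, a macrophage protein, at -2.77, and these became -0.12 and -0.27. Cd74, of antigen presentation, was at -1.43 and -0.37. The macrophage genes Tyrobp, Lyz2 and C1qc, chosen after their values were seen, were above background on the 3 h control, 3 h low-dose and 48 h high-dose arrays and below it on both others. Against both control arrays 116 genes were higher and 60 lower at 2-fold. The share of called genes that were higher was 56.4%, and 40.7% when arrays were centred on their median, which moved the median difference of all measured genes from -0.01 to -0.13.

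**Figure D2:**
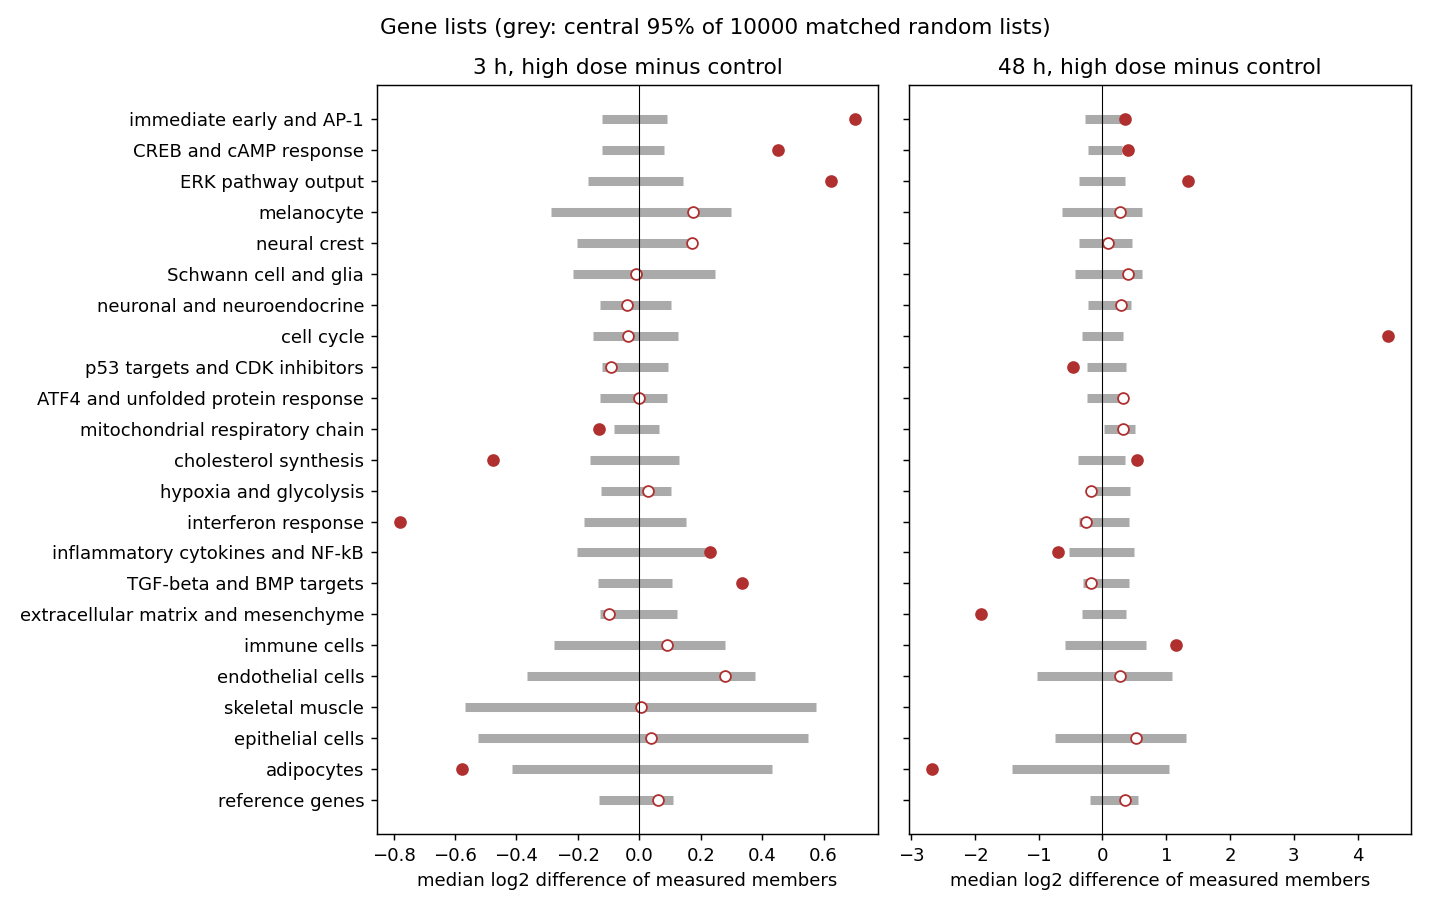
Median log2 difference between high dose and control for each of the 23 gene lists at 3 h (left) and 48 h (right), with the central 95% of 10000 matched random lists in grey and filled points outside it. The cell cycle median was -0.04 at 3 h and 4.47 at 48 h, and a list with under 3 measured members has no point.

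At the low dose, immediate early genes, ERK output, CREB targets and TGF-beta targets were also higher than in the 3 h control, and interferon and cholesterol genes were lower. The median was 0.35 for the immediate early and AP-1 list (6 of 30 higher, 0 lower), 0.45 for ERK output (4 of 23) and 0.21 for CREB and cAMP targets (3 of 28), all at percentile 100. TGF-beta and BMP targets had a median of 0.49 (percentile 100), with 4 of 19 higher, among them Pmepa1 at 3.88, which was 1.48 against the 48 h control. Against that control the ERK list was at 0.71 for the low and 0.49 for the high dose, and the TGF-beta list at 0.47 and 0.49. Plaur, the urokinase receptor, was at 2.83. The interferon list was at -0.48 (1 of 18 lower at 2-fold) and the cholesterol list at -0.44 (1 of 20), both at percentile 0. The latter was at -0.29 against the 48 h control. Genes of matrix and mesenchyme were slightly higher (median 0.19, percentile 100, 3 of 24 at 2-fold), as were Schwann cell and glial genes (0.18, percentile 97.7, 0 of 10). Small downward shifts appeared in the ATF4 list (-0.08, percentile 1.58) and the respiratory chain list (-0.03, percentile 0.730), with 0 members of either at 2-fold. Against the 48 h control the matrix (0.13, percentile 95.5), Schwann cell (0.12, percentile 87.7) and ATF4 (-0.00, percentile 28.6) lists lay inside the random interval and the respiratory chain list turned to 0.17. Against it the neuronal list (0.18, percentile 98.8) lay above the interval, and the hypoxia (-0.14, percentile 0.690) and adipocyte (-0.78, percentile 0.780) lists below. The control arrays differed from each other at 2-fold in 542 of 14018 genes, or 3.87%. At the low dose 189 of 14062 genes, or 1.34%, were called, 82 of them lower. The share of called genes that were higher was 56.6%, 46.8% with arrays centred on their median and 38.8% against the 48 h control. Against both controls 57 genes were higher and 30 lower. Pold3 at 3.95, Nrxn3 at -4.49, Mpp4 at -3.74, Kcnab1 at -3.31 and Dpf1 at -2.54 were among the largest differences, and against the 48 h control they were at -0.06, 0.13, -0.45, -0.45 and 0.14.

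The order of the doses over single genes was not separable from the effect of the shared control array. Of 459 genes called at the high dose and measured on all 3 arrays, the low dose lay between control and high dose for 344, or 74.9% (exact 95% binomial interval 70.7% to 78.8%, over genes, which are not replicates). It lay beyond the high dose for 42 and on the opposite side for 73, and the median ratio of the low to the high log2 difference was 0.392. Restricted to the 175 genes at 2-fold against both controls, the share was 80.0%. In simulated arrays with no change, a shared control and a noise SD of 0.3003 per array, the share was 87.8%, so the share is no evidence of a dose order. That SD came from the spread of the high-dose differences over all genes, which contains any response. In a check chosen after seeing the data, in which no array is shared, the low dose minus the 48 h control had the sign of the high dose minus the 3 h control for 246 of 450 called genes, or 54.7%. Both doses were set against the same control array, which makes their differences resemble each other. The correlation across genes was 0.625, and 0.499 in the same simulation, where the covariance of 0.0899 exceeded the measured 0.0842. The simulated covariance follows from the noise SD, and with noise from the replicate spots it was 0.00393. It therefore cannot decide whether genes responded to both doses. There were 67 genes higher and 42 lower at both doses, against 15.3 and 16.6 in that simulation, whose noise is equal for all genes. With no array shared, 49 genes were higher and 20 lower in both differences, where independence would give 5.40 and 6.11. Opposite signs were found for 37 and 41, where it would give 7.98 and 4.13, and the correlation was 0.0818. The simulation already shares the control, so the excess over it may come from a response to both doses. Noise that is unequal between genes, or genes that vary between cultures, may also account for it, and these were not told apart. Genes are not independent replicates, so these correlations carry no p-value. Across genes, the low dose at 3 h correlated at 0.0526 with the high dose at 48 h, with which it shares no array, and the high dose at 3 h at 0.161.

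The high dose exceeded the low dose at 3 h in the immediate early (median 0.26), CREB (0.34) and ERK (0.23) lists, all at percentile 100. At 2-fold, 6 of 33, 4 of 29 and 4 of 24 members were higher, and 1, 0 and 2 were lower. Against the 48 h control the ERK median was 0.71 at the low and 0.49 at the high dose. These are medians of separate differences and do not subtract, while the direct difference of 0.23 contains no control array. Fos was 6.39-fold higher at the high dose. Matrix and mesenchyme genes were lower at the high than at the low dose, with 6 of 24 at 2-fold and 0 higher (median -0.39, percentile 0). The interferon list was also lower (-0.33, percentile 0), with 0 of 18 members at 2-fold. The neuronal list (-0.16, percentile 0.130, although 2 of 18 members were 2-fold higher and 0 lower), the respiratory chain list (-0.12, percentile 0.820) and 4 adipocyte genes (-0.52, percentile 0.360, and -0.21 at percentile 7.98 without the filter on dim probes) had medians below the random interval. In all 183 genes were higher and 127 lower among 14350. Among the largest differences were Olfr1382 at 4.48, Zfhx2 at 4.09 and Olfr213 at 4.06 upward, and Ctss at -3.92, the retinol dehydrogenase family gene Rdh19 at -3.65, the neuritin gene Nrn1 at -3.39 and the pentraxin gene Ptx3 at -3.33 downward. The levels of Olfr1382, Zfhx2 and Olfr213 were -5.16, -4.14 and -4.87 on the low-dose array. They were also near the dim end on the 48 h high-dose array, at -4.44, -3.25 and -4.01. High-dose levels of Ctss, Rdh19, Nrn1 and Ptx3 at 3 h were -4.79, -5.12, -4.03 and -4.48. Those on the 48 h control array were near them, at -4.67, -4.63, -4.18 and -4.01.

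After 48 h of the high dose, genes of the cell cycle were far higher than in the 48 h control. Of 28 measured members, 27 were at least 2-fold higher and 0 lower, 3 more were higher as bounds, and the median of 4.47 lay above all random lists. Mki67, the proliferation marker, was 116-fold higher (6.86), the cyclin gene Ccna2 76.6-fold (6.26), the mitotic kinesin gene Kif20a 60.5-fold and Rrm2, a subunit of ribonucleotide reductase, 59.7-fold. Ube2c and Nusap1, of mitosis, were at 6.68 and 6.04. The list median against the 3 h control was 4.23. Inhibitors of cell cycle kinases and p53 targets were lower, with 6 of 23 at 2-fold lower and 1 higher (median -0.46, percentile 0.05). Cdkn2b was 16.0-fold lower, Fas, a death receptor gene, at -2.75, and Cdkn2a at -2.03, while Gadd45a, named after its value was seen, was at 1.81.

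Matrix and mesenchymal genes were lower at 48 h of the high dose. Of 22 measured members 15 were lower and 1 was higher, with a median of -1.90 (percentile 0). Postn, encoding periostin, was at -5.58, Thbs1, encoding thrombospondin, at -4.16, lumican (Lum) at -3.63 and Col6a1 at -3.36. Against the 3 h control Postn was at -2.80, and it was higher by 2.78 in the 48 h than in the 3 h control. Other large falls were Ngfr, the neurotrophin receptor gene used as a neural crest marker, at -6.45, Angptl4 at -6.72, Grem1, a BMP antagonist, at -4.83 and Igfbp5, at least 208-fold lower. Neural crest genes as a list did not shift (median 0.08, percentile 54.1), with 4 of 14 lower, such as Snai2 at -2.54 and Twist1 at -2.04, and Sox8 higher at 1.93. The melanocyte (0.28, percentile 81.3), Schwann cell (0.41, percentile 88.0) and neuronal (0.29, percentile 79.3) lists lay inside the random interval. TGF-beta and BMP targets had 8 of 19 lower and 2 higher around a median of -0.19 (percentile 7.80), which was -0.64 (percentile 0.150) after quantile normalisation and -0.76 (percentile 0) against the 3 h control. The hypoxia list was at -0.17 (percentile 5.67), and at -0.53 (percentile 0.520) after quantile normalisation. The ATF4 (0.32), respiratory chain (0.32), endothelial (0.28) and epithelial (0.53) medians lay inside the interval. With bounds included the endothelial median was -0.82, with 3 measured genes and 3 lower as bounds, and the melanocyte median was -0.11. The 2 measured muscle genes were too few to score.

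ERK output was higher at 48 h as at 3 h, with 12 of 23 members higher and 2 lower (median 1.34, percentile 100, and 0.81 against the 3 h control). Areg, encoding amphiregulin, had the largest measured rise among genes with an ordinary symbol, 174-fold (7.44), and Plaur, Etv4 and Epha2 were at 3.71, 3.42 and 3.38. The lower members were Etv1 at -2.81 and Phlda1 at -2.78, named after their values were seen. The immediate early list had 12 of 30 higher and 3 lower (median 0.35, percentile 99.2, and 0.53 against the 3 h control), with Dusp2 at 4.39 and Jun, named after its value was seen, at -2.41. CREB and cAMP targets had 9 of 28 higher and 3 lower (0.41, percentile 99.6, and 0.68 against the 3 h control), including Crem, 5.65-fold higher, and Bdnf, a neurotrophin gene, at -2.94. Cholesterol synthesis was higher, opposite to 3 h, with 6 of 20 at 2-fold and 0 lower (0.54, percentile 99.9). Pmvk and Mvk, kinases of the mevalonate pathway, were at 3.12 and 1.35. Cytokines and NF-kB targets had a median of -0.70 (percentile 0.480), with Relb at -1.68 and Tnfaip3 at 2.65. Of the interferon genes Ifit3 was at -7.21, while the list lay inside the random interval (-0.25, percentile 7.14). Psat1 and Mthfd2, of serine and one-carbon metabolism, were at 2.53 and 2.09. Among 3 measured adipocyte genes Cebpa was at -3.76 and Lpl, lipoprotein lipase, at -2.67 (median -2.67, percentile 0.210, and -0.98 with bounds included). Against the 3 h control Cebpa was at -2.17, Lpl at -1.06 and the list at -1.08, inside the random interval (percentile 3.19).

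Genes of immune cells were also higher on the 48 h high-dose array. Of 7 measured, 4 were higher and 0 lower (median 1.16, percentile 99.8), and 3 more were higher as bounds. Csf1r, the macrophage growth factor receptor, was at 2.41, Cd14 at 1.96 and Fcer1g at 1.36. The bound for Tyrobp was a rise of 4.42 or more. Csf1r was also bright on the 3 h high-dose and 48 h control arrays, at levels of 2.65 and 2.89. Tyrobp was below background on both, so the level of Csf1r did not follow that of Tyrobp there. Ctss was at 6.09, and at 2.20 against the 3 h control. Further large rises were Dnase1l3 at 6.93, Ucp1, the uncoupling protein of brown fat, at 6.67, Prl7b1 at 6.62 and the bound of Cyp3a44, at least 447-fold.

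In all, 1363 genes were higher and 1386 lower at 2-fold at 48 h among 13739 measured, with 436 and 388 at 4-fold and 304 and 414 more as bounds. Against both control arrays 999 were higher and 958 lower. The 48 h high-dose array had the lowest 75th percentile of signal, 0.79 log2 units below the 3 h control (-0.79), while its spike-in probes were at -0.15, and 12 reference genes had a median of 0.36 (percentile 78.7), or 0.01 after quantile normalisation. Other measured probes of a called gene were averaged. They had the same direction for 564 of 624 genes at 48 h and for 67 of 71 at the 3 h high dose. They reached 2-fold in that direction for 387 and 46 genes. At the 3 h low dose the direction was the same for 21 of 25 genes, with 10 at 2-fold.

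**Figure D3:**
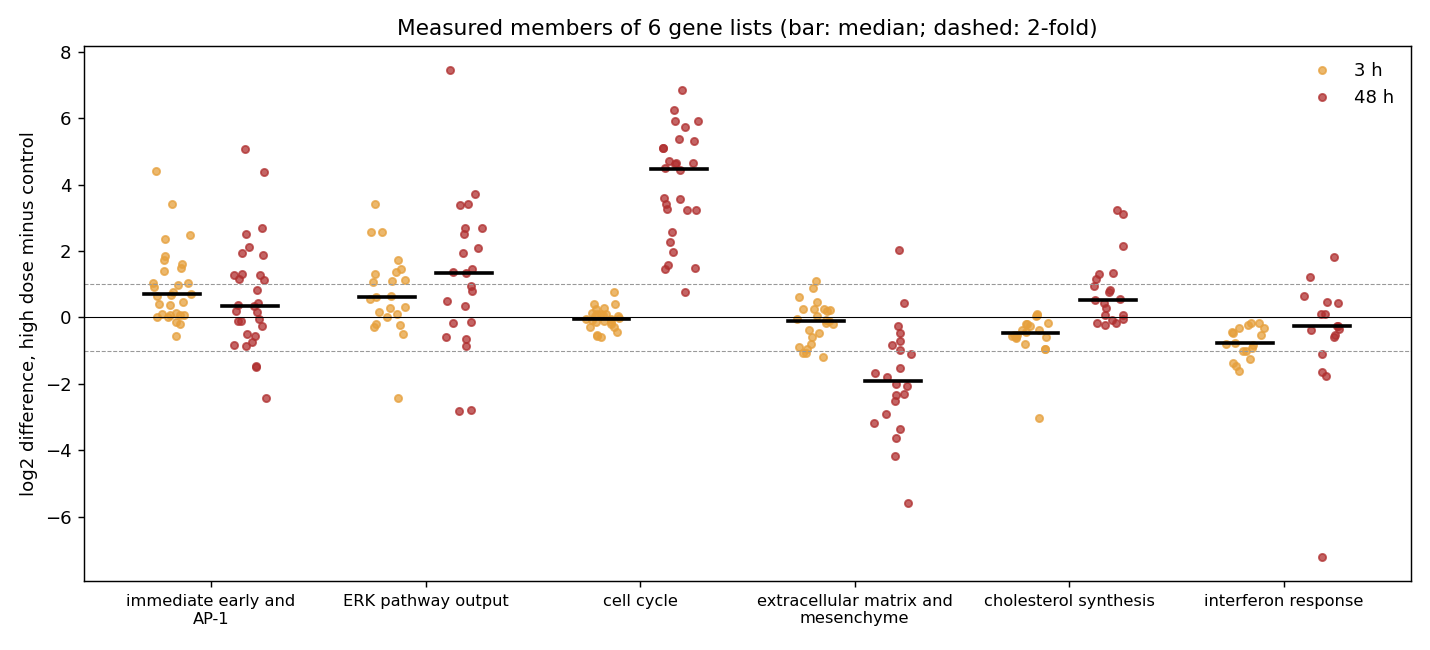
Log2 difference between high dose and control of each measured member of 6 gene lists, at 3 h (orange) and 48 h (red), with 1 point per gene, a bar at the list median and dashed lines at 2-fold. The medians for extracellular matrix genes were -0.10 at 3 h and -1.90 at 48 h, and for cholesterol synthesis -0.48 and 0.54.

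Early and late responses to the high dose overlapped in part. Among 13482 genes measured on all 4 arrays, 99 were higher at both times, where independent lists would give 21.1, and 42 were lower at both, where they would give 16.4. A further 28 were higher at 3 h and lower at 48 h (22.6 by independence) and 34 the reverse (15.3). Across genes the correlation of both responses was 0.161 (Spearman 0.161). In the limma fit of a high-dose effect common to both times, 0 of 14601 genes passed an adjusted p of 0.05 and 501 had an unadjusted p under it. That is a smaller share than the 0.05 to be found if no gene changed. Fos had an effect of 4.74 (SE 0.319), a limma p of 0.000126 and an adjusted p of 0.884. Ewsr1 was at 0.30 (SE 0.255) and Atf1 at -0.09 (SE 0.277). Without the filter on dim probes the fit called 4 genes, all higher: Fos (adjusted p 0.00593), Olfr828 (0.0100), Wdr92 (0.0168) and C2cd4b (0.0314). The eBayes prior then had 8.145 degrees of freedom, against 2.968 with the filter. The SE of Fos was larger in that setting, at 0.360, so its lower adjusted p does not come from a tighter estimate. Olfr828 was below background on both control arrays.

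The control arrays of both times also differed from each other. Of 13472 genes measured on all arrays, 19 stood above and 14 below all other arrays at 2-fold on the 3 h control array, and 83 above and 25 below on the 48 h control array. The 48 h control differed from the 3 h control by 351 genes higher and 191 lower of 14018, or 3.87%. Among the 5 largest rises were 4 glutathione S-transferase genes, Gsta1 at 5.12, Gsta2 at 4.38, Gsta4 at 4.26 and Gsta3 at 3.70. These are close paralogs, and cross-hybridisation between their probes leaves the single values uncertain. Pold3, 16.1-fold higher, Nrxn3 at -4.62, Ctss at -3.89 and Mpp4 at -3.29 were again among the largest differences. Adipocyte genes had a median of 0.86 over 4 members (percentile 99.7), and 0.13 (percentile 66.2) without the filter on dim probes. The respiratory chain (-0.24, percentile 0), neuronal (-0.21, percentile 0.0900), p53 (-0.18, percentile 0.110), ERK (-0.16, percentile 1.08) and neural crest (-0.16, percentile 2.30) lists were slightly lower, the last inside the random interval after quantile normalisation (percentile 5.16), and the cell cycle list was at -0.01 (percentile 37.2). Of the called genes 64.8% were higher, and 49.3% with arrays centred on their median, which put the median of all measured genes at -0.12 in place of 0.01.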

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

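The tests of array scaling, of the 3 h control as reference and of macrophage RNA as the source of opposite signs were chosen only after the results were seen, and the other tests were set beforehand.

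The responses to the high dose had opposite signs at 3 h and 48 h for 4 genes and 2 lists, and the difference between times was not tested, because each time has 1 array per group. The 4 are among the genes reported under the naming rule for the high dose against the control of the same time. Nrn1 (1.07 at 48 h and -2.76 at 3 h) and Etv1 (-2.81 and 1.12), reported above outside that selection, also had opposite signs. At 48 h and 3 h the values were 6.09 and -4.01 for Ctss, 5.40 and -2.77 for Cd5l, 1.16 and -1.43 for Cd74, and 1.27 and -1.14 for Gpnmb. Against the other time's control array they were 2.20 and -0.12 for Ctss, 0.10 and -0.37 for Cd74, and 0.41 and -0.28 for Gpnmb. The cholesterol synthesis list had medians of 0.54 and -0.48, and the cytokine and NF-kB list -0.70 and 0.23. Against the other time's control they were 0.43 and -0.32, and -0.51 and 0.05. The NF-kB list at 3 h then lay inside the random interval, and it was at -0.23 without the filter on dim probes, so its opposite sign was lost there.

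Ctss, Cd5l and Cd74 are genes of macrophages and related cells. Gpnmb is found in such cells too, but in the lists fixed beforehand it is a melanocyte gene. Immune cell genes were higher on the 48 h high-dose array. Of 12 macrophage markers, 9 were above background on that array and 7 were at least 2-fold higher than in the 48 h control, bounds included. This lies between the outcomes set for and against macrophages in that culture, and 6 of the 12 markers are also in the immune cell list. Another test took macrophage RNA in the 3 h control and 48 h high-dose cultures as the source of the opposite signs. Of 9 detected markers, 8 were higher on the arrays of these cultures than on the 3 h high-dose and 48 h control arrays. For 3 of them this compares signals below background, and among 6 markers whose order can be read it held for 5. The order was chosen after such genes had been seen to move, and markers from 1 source are not independent, so no chance level is given. Levels on the 3 h control, 3 h high-dose, 48 h control and 48 h high-dose arrays were -2.75, -7.61, -7.51 and -1.03 for Tyrobp, and -5.00, -7.55, -7.37 and -3.29 for Lyz2. The 3 h low-dose array did not enter this order. Tyrobp and Lyz2 were above background there too, at -3.52 and -5.06. Their signal was thus not limited to the 3 h control and 48 h high-dose arrays. A varying share of macrophages is a candidate explanation, and regulation of these genes in the tumour cells stays open and was not tested.

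The cell cycle genes formed the largest list shift at 48 h. Scaling of the arrays is argued against by their median of 4.51 after quantile normalisation, and a late fall in the 48 h control array by their median of 4.23 against the 3 h control. An effect of the fusion may account for the rise, as may doxycycline itself, culture density or a difference between single cultures, none of which these arrays can separate.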

How the results depend on the processing

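The other time's control array and the use of both controls were chosen after seeing the data. The cause was not tested for any change below unless stated.

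Counts at 2-fold depended most on dim probes. Without a filter 1360 genes were called for the 3 h high dose, 816 for the low dose, 1230 for high against low dose, 4471 at 48 h and 1361 between controls. With signal above background on 1 array or more, the counts were 859, 408, 601 and 915 in the same order without 48 h. More genes enter under both settings. Normexp background with quantile normalisation gave 212, 94, 123 and 270. Against the other control 722 genes were called for the 3 h high dose and 768 for the low dose, and against both controls 176 and 87, where fewer genes can pass by construction.

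The correlation of both times was 0.109 with 1 array above background and 0.0469 without a filter, and the share of genes with the low dose between was 60.4% without a filter. The common effect had 4 calls without a filter and 0 in the other settings, where limma gave 457 to 735 genes at an unadjusted p under 0.05. These are shares of about 0.05 or less, no more than would be found if no gene changed.

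Without a filter the NF-kB list at 3 h of the high dose was at -0.23. Against the other control the respiratory chain list was at 0.0414 for the high and 0.17 for the low dose, and Pold3, Nrxn3 and Dpf1 at -0.0577, 0.13 and 0.14 for the low dose. Of list values 1110 moved by no more than the median spot SD of a log2 difference (0.0887 to 0.0918), and 197 moved further. The 3 above, outside the random interval as reported, changed sign. That SD is not the error of a list median, and some shifts reported as outside the interval are smaller than it. Of named gene values 1591 moved by no more than the gene's scanner error and 268 moved further. The 3 genes above, at 2-fold as reported, changed sign. Counting values under these thresholds too, 111 list values and 12 named gene values changed sign, Atf1 against the other control among them.

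Lists outside the random interval numbered 42 to 46 across settings, 43 as reported. Pairing of replicates within a time was not possible, because each group holds 1 sample. The limma fit, over 4 arrays, pairs high dose with control within each time. Leaving out 1 of these arrays leaves no residual degree of freedom. Slide as a block was not run, since all arrays share 1 slide. Normexp used the median spot signal. Low signal over background limits dim genes to bounds.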

Other observations

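The NRF2 list and the macrophage markers were chosen only after the data were seen, and the tests here were set before their own results were seen.

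On the 3 h control array 33 genes stood apart from all 4 other arrays in the same direction, 19 higher and 14 lower. The counts were 83 and 25 on the 48 h control array, 7 and 7 on the 3 h low-dose, 18 and 3 on the 3 h high-dose and 775 and 781 on the 48 h high-dose array. Other measured probes, available for 5 of them, had a median difference of 0.38 in the direction of the call, between the values set for and against a spot artefact on single probes. They shared the difference for Pmepa1 (-3.14 and -3.29) and Skil (-1.41 and -1.76) and not for Pilra (1.68 and -0.26) or Zfp157 (-1.23 and 0.04). For Dpf1 the second probe differed by 0.38 in the direction of the call, which is under 2-fold, so it did not share the size of the difference. The mean levels of Pmepa1 and Skil were 1.09 and 0.62. The median level of the 33 genes lay at percentile 19.2 of all measured genes, between the values set for and against dim probes. Spot artefacts, dim probes and a real difference of that culture cannot be told apart for the genes without a second measured probe, since the array has no replicate. For Pmepa1 and Skil the shared difference on a second probe speaks against a single-probe artefact.

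The glutathione S-transferase genes higher in the 48 h control led to the hypothesis that NRF2 target genes rise together between the control arrays. The median of 12 NRF2 targets was 1.04, at percentile 100 of matched random lists, with 6 at 2-fold higher and 0 lower, among them Gstm1 at 2.62 and Gclc at 1.85. Of the 12, 1 is also in a list fixed beforehand. Activation of NRF2 during culture may account for this, and whether medium, density or time is behind it was not tested. At 48 h the high dose was lower than the control for Gsta1 (-4.34) and Gstm1 (-3.23), while the NRF2 list median was -0.25 (percentile 3.87).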
